A study of Mus musculus with 4 samples.

How the data were processed

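Gene expression was measured in 4 cultures of mouse dendritic cells (DCs) grown from BALB/c bone marrow, with 1 one-colour Agilent array per culture. Immature DCs (imDCs) were, per the labels' protocols, the loosely adherent clusters left on day 4 of a marrow culture in GM-CSF (10 ng/mL) and IL-4 (5 ng/mL), selected on magnetic beads for CD11c, an integrin carried by most DCs. Mature DCs (maDCs) were such imDCs kept for 4 to 5 more days with 10 ng/mL of lipopolysaccharide (LPS), a bacterial product that triggers DC maturation. The third culture, here called sDCs as in the labels, grew from lineage-depleted haematopoietic progenitors on a monolayer of mesenchymal stem cells (MSCs), a stromal cell type, received LPS on day 4 and was collected as formed on day 9. The fourth was made in the same way with a neutralizing antibody against IL-10 added at 10 µg/mL every 2 days. The labels call all 4 populations purified, but how the sDCs were separated from the stromal layer is not given in the sources used here. RNA was extracted with Trizol and columns, and 0.5 µg was amplified and labelled with the dye Cy3, per the labels' protocols.

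The authors deposited 1 scanner table per array, with a background-subtracted intensity for each spot. Per the file headers, these intensity values came from Agilent Feature Extraction 10.5.1.1, with spatial and multiplicative detrending on, surrogate values for dim spots and probe positions in the mouse build mm9, while the submitters' processing notes name version 9.1. The authors also deposited a value table, which the comparison with the scanner values showed to be on a log2 scale: each column correlated with log2 intensity at 0.997 (imDC), 1.00 (maDC), 0.999 (sDC) and 0.999 (antibody-treated sDC) across probes. The 4 columns shared 1 distribution, with a median of 6.30 each and quantiles within 0.00149 of those of the imDC column, which is what quantile normalization gives. Genes were not centred in it, and since each array held 1 sample, no ratio direction was open.

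From the scanner tables, log2 of the processed intensity was taken, and the 75th percentile of each array's non-control spots was subtracted. Control spots and spots with an outlier mark were left out (76, 132, 117 and 148 spots on the imDC, maDC, sDC and antibody arrays), spots of 1 probe were averaged, and a probe counted as well above background where at least 50% of its spots were marked so by the scanner software. No spot was saturated (0 on each array). Each array held 43379 such spots for 41174 probes. Spots well above background made up 69.7% on the imDC array, 61.2% on the maDC array, 66.0% on the sDC array and 63.4% on the antibody array. Of 245 probes spotted 10 times on each array, the 172, 166, 172 and 162 with at least 8 usable spots, all well above background (imDC, maDC, sDC and antibody arrays), had a median SD between spots of 0.059, 0.047, 0.056 and 0.054 log2 units. This covers spotting and scanning only, not culture, RNA or labelling.

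Probes were named through a RefSeq gene table of the assembly GRCm38.p6, used for names alone: 25097 through an accession, 6333 through a symbol and 1640 through a synonym held by 1 gene, while 8104 had no match. This gave 19822 genes, 8708 of them with more than 1 probe. Each gene was represented by the probe with the highest mean log2 signal over the 4 arrays. Where a probe was well above background on 1 of the arrays compared, the difference was taken as a bound, with the dim side set at the higher of its own signal and the lowest signal among probes well above background, and is written as "at least". Probes that were dim on both arrays gave no value. Genes with near-identical copies (Hspa1a and Hspa1b, the haemoglobins, the classical and non-classical MHC class I genes, Chil3 and Chil4, the Ear family) may share probe signal, so their values are uncertain.

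The comparisons were maDC minus imDC, sDC minus imDC, sDC minus maDC, and antibody-treated sDC minus sDC. With 1 array per group there is no estimate of the spread between cultures, so no p-value or standard error is given, the intervals printed cover the spread over genes and not that between cultures, the number of arrays limits the precision, and genes are counted at a fixed size of 2-fold (a log2 difference of 1). The imDC array lay on another slide, with another scan, than the other 3, so slide and group cannot be told apart in the comparisons with imDCs. The remaining 3 arrays shared 1 slide.

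The groups, the 2-fold threshold, the gene lists, the alternatives and the rule for named genes were set before the data were examined. The rule took, per comparison, the 10 genes with the largest difference in each direction that were measured on both arrays and had no other measured probe 2-fold or more the opposite way, the 3 largest bounds in each direction, up to 4 members of each list with the largest differences, and 16 genes in every comparison (Il10, Il10ra, Socs3, Stat3, Il12a, Il12b, Il6, Tnf, Il1b, Cd80, Cd86, Cd40, H2-Ab1, Ccr7, Itgax, Irf8). There were 27 lists. The 14 process lists covered costimulation and maturation, MHC class II, MHC class I, proinflammatory cytokines, chemokines, IL-10 and STAT3 signalling, regulatory genes, Notch, interferon-stimulated genes, NF-kB targets, toll-like receptors, cell cycle, glycolysis and hypoxia, and cholesterol synthesis. The 12 cell type lists covered DCs, plasmacytoid DCs, macrophages, osteoclasts, stromal cells, neutrophils, mast cells and basophils, eosinophils, B cells, T and NK cells, erythroid cells and megakaryocytes, and progenitors, and 1 list covered heat shock and handling. A list's median was taken with bounds at their value, and "or lower" or "or higher" marks a median that the bounds leave open on that side. Each list's median difference was placed among 10000 random lists of the same size matched on mean expression. The percentile describes these arrays and is not a test.

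The alternatives were quantile normalization, normexp background correction with an offset of 50 in limma, no filter on dim probes, only probes well above background on all 4 arrays, the mean over a gene's probes, and the authors' value table. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The steps were tested on simulated data made from the sDC array and a copy of it with spot noise (19815 genes): all 100 genes set to a log2 difference of 1.5 and all 100 set to 3 were recovered at 2-fold, and 0 of 14230 genes left as they were passed it. Of 200 random lists of such genes, 9 (4.5%) fell outside the middle 95% of matched lists. The changed genes were drawn only from those far above background, and spot noise was small beside 2-fold. The recovery thus checks the steps alone, and not dim probes, bounds, or noise of labelling and culture.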

Results

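Expression profiles were compared between 4 populations of mouse bone marrow-derived cells: immature DCs, LPS-matured DCs, DCs formed on mesenchymal stroma and then exposed to LPS (sDCs), and sDCs formed in the presence of an antibody that neutralizes IL-10. Each population was represented by 1 array, so there are no replicates, and every value below is a difference between single arrays in log2 units of normalized signal unless given as a fold. Over the 12946 genes well above background on all 4 arrays, the sDC and the antibody-treated sDC profiles lay closest together, with an SD of their differences of 0.25 and a correlation across genes of 0.996. The SD was 1.15 between imDCs and maDCs, 1.30 between maDCs and sDCs, and 1.57 between imDCs and sDCs. For the antibody-treated sDCs it was 1.53 against imDCs and 1.31 against maDCs.

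The first comparison asked how LPS-matured DCs differed from immature DCs. The maDCs had also been cultured for longer, and no culture kept as long without LPS was among the samples. The imDC array also lay on another slide, and markers of neutrophils, eosinophils, mast cells and basophils differed between the arrays, as given below. LPS, the longer culture, the slide and a different makeup of cells therefore cannot be told apart in the differences between maDCs and imDCs. Several inflammatory genes were far higher in maDCs: Il12b, which encodes the p40 subunit shared by IL-12 and IL-23, was higher by 9.27 (617-fold, probe at mm9 chromosome 11, 44227121 to 44227180), Csf2, which encodes GM-CSF, by 6.95 and Ifng by 6.87. The largest measured difference was in Hamp, the gene of the iron-regulating hormone hepcidin, at 9.53 (740-fold, chromosome 7, 31727490 to 31727549). The scavenger receptor gene Marco was higher by 7.28, and the acute-phase and complement genes Saa1 and Cfb by 6.43 and 6.27. Mgarp and Tph1 were higher by 6.71 and 6.31. In the other direction, Fgf22, a fibroblast growth factor gene, was at least 1183-fold lower, and the genes measured on both arrays included those of neutrophil granules, with Ltf (lactoferrin) at -7.50, Ngp at -7.44, Camp (cathelicidin) at -6.77 and Elane (neutrophil elastase) at -5.57. Cd177, a neutrophil surface antigen, had the most negative measured value at -8.02 with 1 probe per gene (chromosome 7, 25531261 to 25535362), while another probe of Ltf gave -8.32.

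By list, the proinflammatory cytokines had a median of 3.38 (percentile 100 among matched random lists), with 14 of 16 members at least 2-fold higher and none lower. Besides Il12b these included Il1a (6.25), Il6 (4.64) and Il1b (3.61), and Csf3, which encodes the granulocyte growth factor G-CSF, was at least 269-fold higher. Of 21 chemokine genes, 19 were at least 2-fold higher (median 3.18, percentile 100), among them Cxcl1 (6.01), Cxcl3 (4.85) and Ccl5 (4.39). All 25 interferon-stimulated genes were at least 2-fold higher (median 2.64, percentile 100), with Rsad2 at 4.78, Gbp2 at 4.68 and Ifit3 at 4.52. In the costimulation and maturation list 18 of 19 genes were at least 2-fold higher and 1 (Icosl, 0.84) lay within 2-fold (median 1.69, percentile 100). Cd40, the receptor for T cell help, was higher by 3.15, Cd86 by 1.59, Cd80 by 1.18 (0.98 on another probe) and the lymph node homing receptor Ccr7 by 1.94. NF-kB targets showed 12 of 14 members higher (median 1.67, percentile 100), with Rel at 2.64 and Tnfaip3 at 2.26.

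Antigen presentation genes differed less. The MHC class I list had 8 of 14 members at least 2-fold higher (median 1.18, percentile 99.97), with Tapbp at 2.05 and H2-K1 at 1.94. The class II list had 5 of 15 higher and 10 within 2-fold (median 0.53, percentile 94.6). The 5 were H2-Oa (1.74), H2-Ob (1.25) and the protease genes Ctsl (2.32), Lgmn (1.39) and Ctss (1.35). The class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 were at -0.19, -0.13 and -0.02. Other probes of H2-Ab1 gave -1.10 to -0.79.

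Il10 itself was 4.05 higher in maDCs (chromosome 1, 132920943 to 132921002), and Socs3, a feedback inhibitor of cytokine signalling induced through STAT3, was 2.64 higher (chromosome 11, 117827480 to 117827539). In the IL-10 and STAT3 list 9 of 17 genes were at least 2-fold higher and 1, Tyk2 at -1.13, lower (median 1.19, percentile 99.99). Stat3 was higher by 1.42 and Il10ra by 1.19. Regulatory genes had 15 of 26 higher and 2 lower (median 1.34, percentile 100). Nos2, the inducible nitric oxide synthase, was at least 67.8-fold higher, Ptgs2 (cyclooxygenase 2) 5.59 and Arg1 (arginase 1) 5.11. Of 14 Notch pathway genes 11 were at least 2-fold higher (median 1.94, percentile 99.97), with the targets Dtx1 and Nrarp at 3.97 and 3.53. The toll-like receptor list had 4 of 20 higher and 2 lower (median 0.29, percentile 67.7), and Cd14, the LPS co-receptor, was higher by 3.05.

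Cell cycle genes were lower in maDCs, with 20 of 25 at least 2-fold lower and none higher (median -1.69, percentile 0). Bub1b, a spindle checkpoint kinase, was at -2.79 and the mitotic motor gene Kif11 at -2.76. Of 20 glycolysis and hypoxia genes 8 were higher, led by Adm at 3.70 and Vegfa at 2.78 (median 0.53, percentile 97.4). Macrophage markers were mixed, with 12 of 20 higher and 3 lower (median 1.24, percentile 100), Cx3cr1 at 3.09 and the mannose receptor gene Mrc1 at -3.04. DC identity genes had 6 of 16 higher and 4 lower (median 0.66, percentile 94.6), with the DC transcription factor gene Irf8 at 2.50 and Itgax, which encodes CD11c, at 0.77.

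Markers of other marrow cells differed between the same arrays. In the neutrophil list 11 of 15 genes were at least 2-fold lower in maDCs (median -4.03, percentile 0), and 5 of 7 eosinophil genes were lower (median -2.02, percentile 0.02), including Ear6 at -5.19. All 10 mast cell and basophil genes were higher (median 2.85, percentile 100), with Cma1, a mast cell chymase, at 4.54 and the IgE receptor chain gene Fcer1a at 4.18. The handling list, made of heat shock and immediate early genes, also lay higher, with 10 of 14 members at least 2-fold higher (median 1.59, percentile 100), Hspa1a at 4.67 and Fosb at 2.21. Stromal markers had a median of 0.29 (percentile 41.7), with 9 of 22 higher and 1 lower. The largest differences in that list were Lox and Dcn, each higher by 5.02 in maDCs. Col3a1 was at least 10.9-fold and Lum at least 6.94-fold higher.

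In all, 3045 genes were at least 2-fold higher and 1518 lower in maDCs among 14111 with a value, 2828 and 1389 of them measured on both arrays, so 66.7% of the differences were towards maDCs. That split depended on the scaling: under quantile normalization the counts were 2404 and 1950 (55.2% higher), and with the authors' deposited values 2534 and 1966 (56.3%), since quantile normalization moves the median gene from 0.19 to 0.00. Matched random lists carry the same shift, so the percentiles above are relative to it. Of 1424 genes past 2-fold with another measured probe, every other probe had the same direction in 90.5%.

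**Figure D1:**
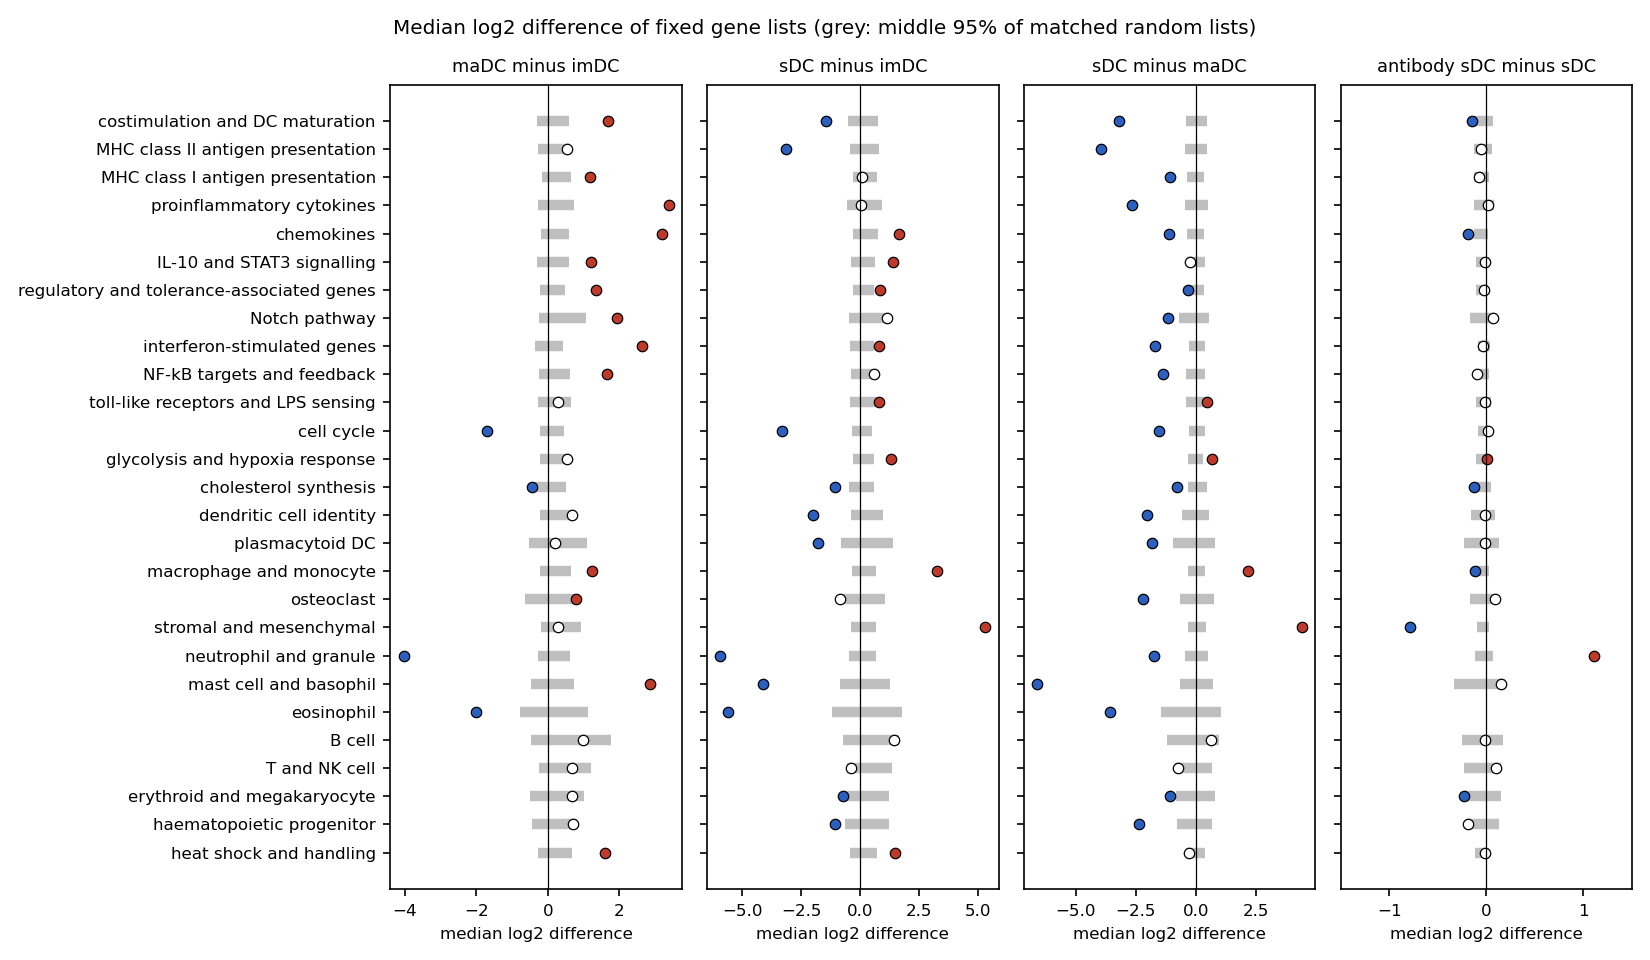
Median log2 difference of each fixed gene list (points) in the 4 comparisons, beside the middle 95% of matched random lists (grey bars), with filled points outside that range, red above and blue below. Costimulation genes lie at 1.69 for maDC minus imDC and at -3.19 for sDC minus maDC, while for antibody-treated sDC minus sDC the stromal list lies at -0.78 and the neutrophil list at 1.10.

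The comparison of sDCs with imDCs asked how LPS-exposed cells formed on stroma differed from conventional immature DCs without LPS. Besides the stromal layer and LPS, the starting cells and the days of culture differed. GM-CSF and IL-4 are recorded for imDCs but not for sDCs. These factors and the slide cannot be told apart in the differences between sDCs and imDCs. Several extracellular matrix genes were among those far higher in sDCs: Dcn (decorin) by 10.16 (1142-fold, chromosome 10, 96980233 to 96980292), Fbln2 (fibulin 2) by 9.53, Col1a1 by 8.16 and the lysyl oxidase-like gene Loxl1 by 8.06, and Col3a1 was at least 4248-fold higher. Several genes typical of tissue macrophages were also higher, including F13a1 (8.60), C1qc (6.99) and Apoe (6.22), and Folr2 was at least 2050-fold higher. Lower in sDCs were the chitinase-like genes Chil4 (-13.22, chromosome 3, 106006764 to 106007043) and Chil3 (-9.97), the chemokine gene Ccl17 (-10.51), the lectin gene Mgl2 (-9.12) and the eosinophil granule gene Prg2 (-9.77). Plet1 was at -11.38, with -6.47 on another probe.

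MHC class II transcripts were lower in sDCs: 10 of 15 list members were at least 2-fold lower and 4 higher (median -3.14 or lower, percentile 0). H2-Aa was at -6.99 (chromosome 17, 34420627 to 34420686), H2-Eb1 at -6.37, the invariant chain gene Cd74 at -5.76 and Ciita, the master regulator of class II transcription, at -5.81. The 4 higher members were the lysosomal protease genes Lgmn (3.32), Ctsl (3.22) and Ctss (1.96) and the ubiquitin ligase gene Marchf1 (2.40). Of 19 costimulation and maturation genes 11 were lower and 5 higher (median -1.46, percentile 0), with Ccr7 at -4.74, Cd80 at -2.21, Cd86 at -1.60 and Cd40 at -1.46, against Tnfsf9 at 4.79 and Cd274, which encodes PD-L1, at 1.05. DC identity genes followed, with 11 of 17 lower and 3 higher (median -1.98 or lower, percentile 0): Itgax was at -4.53 (-2.38 on another probe), Batf3 at -4.06 and Irf4 at least 93.4-fold lower, whereas Irf8 was 1.65 higher (0.85 on another probe).

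Macrophage and monocyte markers were higher in 19 of 20 cases (median 3.23, percentile 100), the exception being Ly6c1 at -4.19. The fractalkine receptor gene Cx3cr1 was higher by 5.83. The stromal list lay at 5.29 (percentile 100), with 21 of 26 genes at least 2-fold higher and 3 lower, and these marker sets differed between the same arrays as the class II and DC identity genes. Neutrophil genes (13 of 15 lower, median -5.92, percentile 0), mast cell and basophil genes (10 of 10 lower, median -4.09, percentile 0) and eosinophil genes (6 of 7 lower, median -5.58 or lower, percentile 0) were lower.

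The IL-10 and STAT3 list had 11 of 18 genes higher and 2 lower (median 1.41, percentile 99.98). Socs3 was higher by 2.82, Il10 by 2.49, Stat3 by 1.50 and Il10ra by 1.31, and the scavenger receptor gene Cd163 was at least 44.9-fold higher, while Socs1 was at -3.67. Regulatory genes had 12 of 26 higher and 3 lower (median 0.86, percentile 99.8), with Arg1 at 7.57 and Hmox1 (haem oxygenase 1) at 4.17, against Aldh1a2, a retinoic acid-producing enzyme, at -8.54 and Pdcd1lg2, which encodes PD-L2, at -6.38. Proinflammatory cytokines split, with 4 of 14 higher and 5 lower: Il18 was at 4.95 and Il1b at 1.04, Il12a at -3.18 and Il6 at -1.57, with Il12b at -0.03 and Tnf at 0.76. Their median of 0.05 (percentile 34.5) turned to -0.07 under quantile normalization, and that of the MHC class I list, 0.08 (percentile 30.9, 5 of 14 higher and 1 lower), turned to -0.12. Chemokines had 13 of 21 higher and 5 lower (median 1.66, percentile 100), among them Ccl8 at 5.64 and Cxcl1 at 5.46.

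Of the remaining process lists, cell cycle genes were at least 2-fold lower in 24 of 25 cases (median -3.32, percentile 0), with Kif11 at -5.20. Glycolysis and hypoxia genes were higher in 11 of 20 (median 1.30, percentile 100), led by Ankrd37 at 4.84 and Adm at 4.52. Interferon-stimulated genes had 10 of 25 higher and 1 lower (median 0.81, percentile 99.5), NF-kB targets 2 of 14 higher and 3 lower (median 0.58, percentile 94.1), toll-like receptors 8 of 20 higher and 2 lower (median 0.81, percentile 99.0) and Notch genes 7 of 12 higher and 2 lower (median 1.13, percentile 95.9), with Jag1 at 4.79. The handling list again lay higher (8 of 14, median 1.46, percentile 100).

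Across the arrays, 3817 genes were at least 2-fold higher and 2422 lower in sDCs than in imDCs, of 15038 with a value. Under quantile normalization the counts were 3124 and 2903, and with the authors' deposited values 3216 and 2911, so most of the excess of higher genes depended on the scaling. The median gene lay at 0.21, and at 0.03 under quantile normalization. Slide and group cannot be told apart here, and among 1976 genes past 2-fold with another measured probe, 83.0% had every other probe in the same direction while 89 had one 2-fold or more the opposite way.

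**Figure D2:**
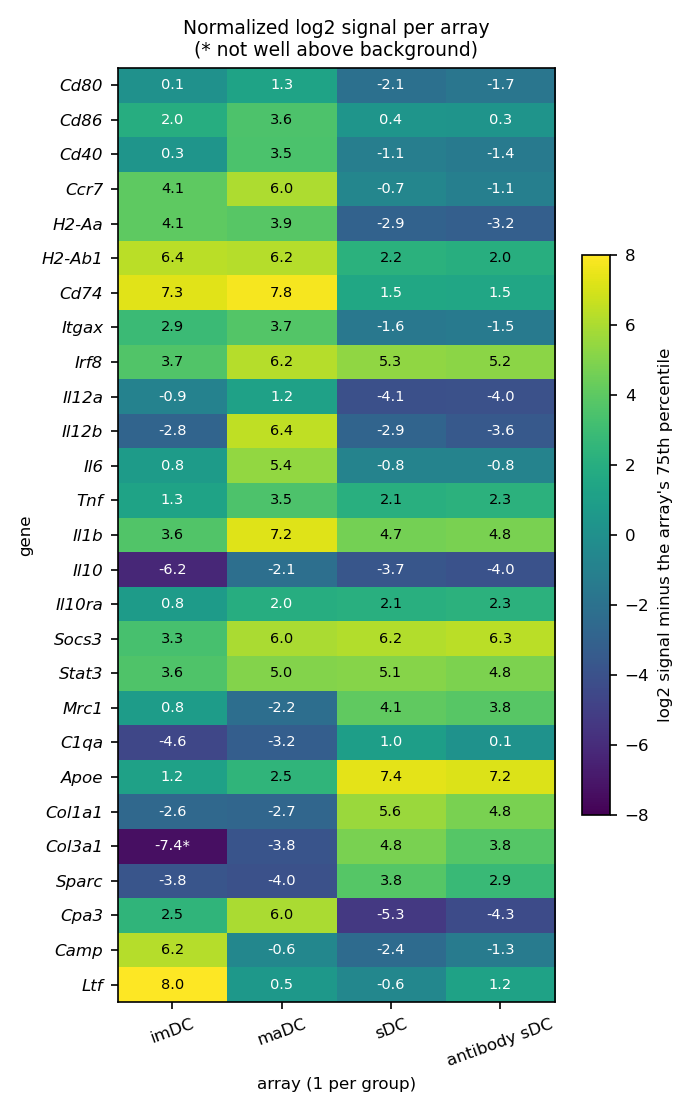
Normalized log2 signal of 27 genes on the 4 arrays (1 per group), relative to each array's 75th percentile, with an asterisk where the probe was not well above background. H2-Aa lies at 4.05 in imDCs, 3.86 in maDCs, -2.94 in sDCs and -3.16 in antibody-treated sDCs, and Socs3 at 3.33, 5.97, 6.15 and 6.32.

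Since sDCs and maDCs had both received LPS and their arrays shared a slide, this comparison asked how the 2 LPS-exposed populations differed. They were not otherwise matched, as the starting cells and the stromal layer differed. GM-CSF, IL-4 and the LPS dose are recorded for maDCs but not for sDCs. These factors cannot be told apart in the differences below. Maturation genes were much lower in sDCs, with 15 of 19 members of the costimulation list at least 2-fold lower and 2 higher (median -3.19, percentile 0). Ccr7 was at -6.68, Cd40 at -4.60 (chromosome 2, 164896301 to 164896360), Cd80 at -3.39 and Cd86 at -3.19, while Tnfsf9 and Cd70 were higher by 2.28 and 1.09. In the class II list 9 of 15 were lower and 2 higher (median -3.93 or lower, percentile 0), H2-Aa being 111-fold lower (-6.80), Cd74 at -6.28 and H2-Ab1 at -4.00. The 2 higher members were Lgmn (1.92) and Marchf1 (1.49). The class I list had 8 of 14 lower and none higher (median -1.07, percentile 0.01), the peptide transporter gene Tap1 being at -1.45.

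Transcripts of inflammatory mediators were lower as well. Of 16 cytokine genes 14 were at least 2-fold lower (median -2.65, percentile 0): Il12b was 631-fold lower (-9.30), Il1a at -7.95, Il6 at -6.22, Il12a at -5.28, Il1b at -2.57 and Tnf at -1.47. Il18, at 3.57, was the only member 2-fold higher. Among the chemokines 11 of 21 were lower and 1, Ccl8 at 1.76, higher (median -1.13, percentile 0). Ccl17, a ligand of the chemokine receptor CCR4, was at -12.20 (chromosome 8, 97335770 to 97335829) and Ccl22, another CCR4 ligand, at least 579-fold lower. Interferon-stimulated genes were lower in 21 of 25 cases and higher in none (median -1.70, percentile 0), with Oasl1 at -4.58 and Rsad2 at -3.68. NF-kB targets were lower in 8 of 14 and higher in none (median -1.38, percentile 0), with Rel at -4.65 and Nfkb1 at -2.42. Toll-like receptors had 5 of 20 higher and 1 lower (median 0.45, percentile 97.9), with Tlr8 at 3.23.

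The genes of IL-10 signalling went both ways. Socs3, Stat3 and Il10ra lay within 2-fold of maDCs, at 0.18, 0.08 and 0.11, and Il10 was at -1.56. The list had 4 of 18 genes higher and 4 lower (median -0.25, percentile 10.2), Cd163 being at least 12.6-fold higher and Socs1 at -4.29. Regulatory genes had 5 of 26 higher and 9 lower (median -0.32, percentile 2.23), with Vsir at 2.71, the phagocytic receptor gene Mertk at 2.58 and Arg1 at 2.46, against Aldh1a2 at -8.73 and Pdcd1lg2 at -7.32. Notch genes had 2 of 14 higher and 8 lower (median -1.18 or lower, percentile 0.29), but over the genes well above background on all 4 arrays the median was 0.31. Cell cycle genes were lower in 17 of 25 (median -1.54, percentile 0), with Bub1 at -3.39 (-0.49 on another probe). Glycolysis and hypoxia genes were higher in 6 of 20 and lower in none (median 0.68, percentile 100), with Pdk1 at 3.02 and Ankrd37 at 2.62.

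In cell type markers, sDCs again combined stromal and macrophage transcripts. The stromal list had 18 of 26 genes at least 2-fold higher (median 4.39 or higher, percentile 100), with Col3a1 at 8.61 (390-fold, chromosome 1, 45405589 to 45405648), Col1a1 at 8.25 (chromosome 11, 94813075 to 94813134) and Sparc at 7.81. The 3 lower members were Mmp2 (-2.21), Thy1 (-1.92) and Vcam1 (-1.57). Outside the list, Ccn2 was at 8.57, Fbln2 at 7.78, Col8a1 at 7.08 and Gas6, a ligand of Mertk, at 6.44. Macrophage markers were higher in 15 of 20 and lower in 2 (median 2.15, percentile 100): Mrc1 at 6.27, Apoe at 4.92 (chromosome 7, 20281732 to 20281791) and C1qa at 4.24, against Marco at -3.76 and Ly6c1 at -1.62. DC identity genes were lower in 9 of 15 and higher in 1 (median -2.05 or lower, percentile 0), with Itgax at -5.30 (-3.72 on another probe), Zbtb46 at -3.29 and Irf8 at -0.85. All 10 mast cell and basophil genes were lower (median -6.60, percentile 0), Cpa3 (mast cell carboxypeptidase) at -11.32 (chromosome 3, 20115674 to 20115733) and Prss34 at -9.01. Eosinophil genes were lower in 6 of 7 (median -3.56 or lower, percentile 0.01), and neutrophil genes lower in 9 of 15 and higher in 4 (median -1.77, percentile 0). Gzmb, Syt7 and Car2 were at -9.46, -9.16 and -8.94.

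Altogether 2080 genes were at least 2-fold higher and 2453 lower in sDCs than in maDCs, of 14603 with a value, 1694 and 1964 of them measured on both arrays. The median gene lay at 0.01. Where another probe of a gene past 2-fold was measured (1291 genes), every other probe had the same direction in 84.7%.

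**Figure D3:**
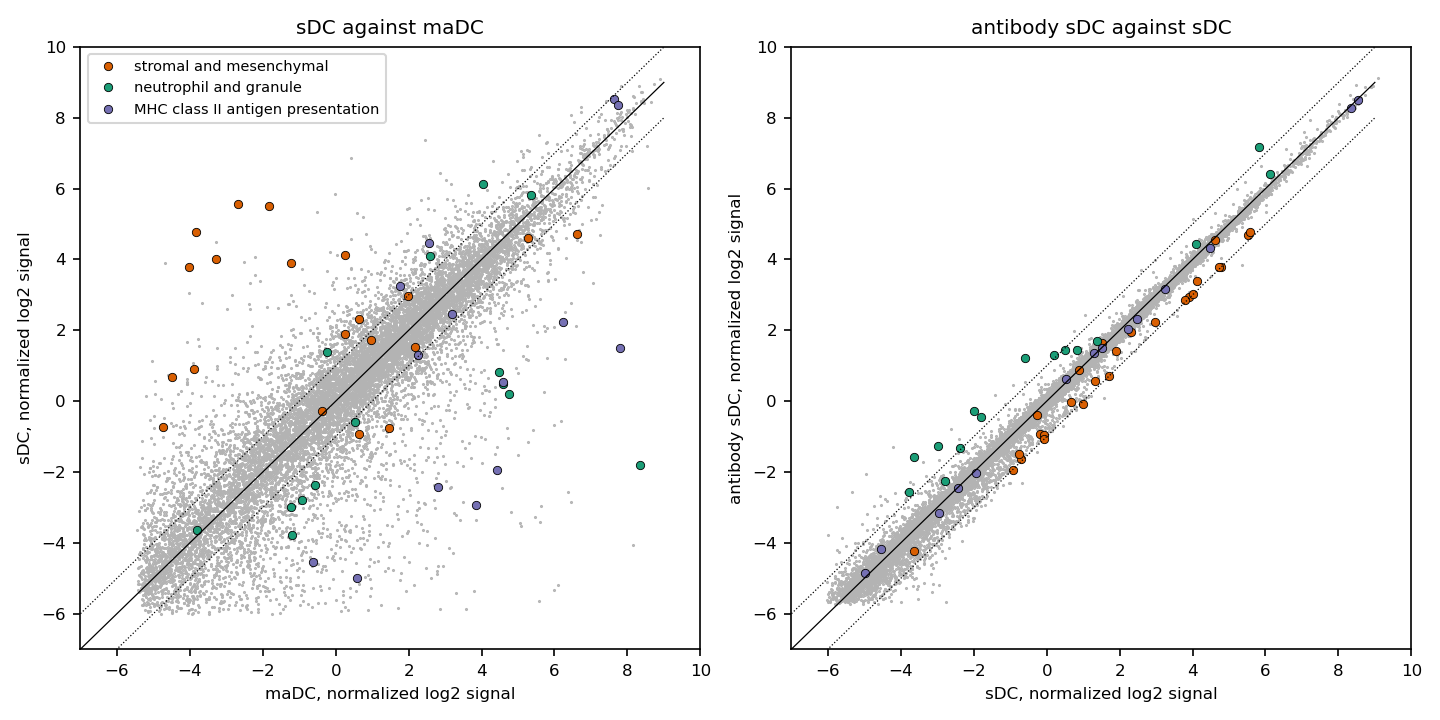
Normalized log2 signal of each gene (grey) in sDCs against maDCs (left) and in antibody-treated sDCs against sDCs (right), with stromal, neutrophil and MHC class II list members coloured, a solid line at equality and dotted lines at 2-fold. Only genes measured on both arrays are drawn. With bounds included, the stromal list has a median difference of 4.39 or higher on the left and -0.78 on the right, where the neutrophil list has 1.10.

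The last comparison asked which genes of sDCs differed when the IL-10 antibody was present during their formation. How far the antibody blocked IL-10 was not measured on these arrays. Few were 2-fold apart: 124 genes were at least 2-fold higher and 181 lower in antibody-treated sDCs, of 14391 with a value, and only 60 and 110 of them were measured on both arrays. These counts depended on the processing: they were 44 and 44 with normexp, 47 and 65 for probes well above background on all 4 arrays, and 309 and 584 with no filter on dim probes. Neutrophil and granule transcripts had the highest list median, with 9 of 15 at least 2-fold higher and all 15 above 0 (median 1.10, percentile 100): Cxcr2, a neutrophil chemokine receptor, was at 2.06 (1.56 on another probe), Ltf at 1.81 (1.90 on another probe), Retnlg at 1.72 and Ngp at 1.71. Stromal transcripts were lower together, with 25 of 26 below 0 and 3 at least 2-fold lower (median -0.78, percentile 0), among them Postn (periostin) at -1.09, Vcam1 at -1.01 (-0.76 on another probe) and Serpinh1 at -1.01, with Col3a1 at -0.98 and Col1a1 at -0.80.

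Most of the maturation and antigen presentation genes that separated sDCs from maDCs lay close to their sDC level. None of 14 class II genes was 2-fold apart (median -0.05, percentile 38.0), with H2-Ab1 at -0.19, and none of 14 class I genes (median -0.07, percentile 28.6). The costimulation list had 2 of 17 lower and none higher (median -0.14, percentile 0.92): Tnfsf4, which encodes OX40 ligand, was at -2.23 (chromosome 1, 163348095 to 163348153) and Cd70, a ligand of CD27, at -1.69, while Cd40, Cd80, Cd86 and Ccr7 were at -0.25, 0.37, -0.08 and -0.39. None of 13 cytokine genes (median 0.02, percentile 81.4), 25 interferon-stimulated genes (median -0.03, percentile 36.1) and 14 NF-kB targets (median -0.10, percentile 9.47) was 2-fold apart. Of 18 chemokine genes (median -0.19 or lower, percentile 0) none was shown to be 2-fold apart, 1 of them being a bound. Il12a was at 0.09, Il12b at -0.70, Il6 at -0.03, Tnf at 0.18 and Il1b at 0.11.

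In the IL-10 and STAT3 list 1 of 18 genes was 2-fold apart, Ddit4, a stress-induced inhibitor of mTOR signalling, at 1.11 (median -0.01, percentile 83.6). Socs3 was at 0.17, Stat3 at -0.26, Il10ra at 0.18 and Il10 at -0.25. The median's sign turned in 4 of 6 alternatives, among them quantile normalization and the authors' table (0.03 in each). Of 25 regulatory genes Aldh1a2, at -1.07, was 2-fold apart (median -0.02, percentile 71.7), while Pdcd1lg2, not well above background with the antibody, was at least 1.50-fold lower. Of 11 Notch genes (median 0.07) none was shown to be 2-fold apart, but Hey1 was at least 1.61-fold lower. No member of the toll-like receptor (20 genes, median -0.02), cell cycle (25 genes, median 0.02) or glycolysis and hypoxia lists (20 genes, median 0.01) was 2-fold apart. Among 20 macrophage genes none was 2-fold apart, though the median of -0.12 lay low among random lists (percentile 0.84), with the complement genes C1qc and C1qa at -0.94 and -0.86. DC identity genes had a median of -0.01, turning positive in 5 of 6 alternatives (0.01 under quantile normalization and in the authors' table), with Itgax at 0.12 and Irf8 at -0.14. The handling list lay at -0.01 and mast cell and basophil genes at 0.15, 2 of 8 being higher (Cma1 1.41, Hdc 1.31). Of the eosinophil genes only Prg2 (1.55) and Ccr3 (0.12) had a value.

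Several of the largest single differences lay in genes outside these lists. Rab27a was at 2.91 on the probe used but at 0.10 on another, and Tmprss3, Aire and Foxe3 were at 2.90, 2.77 and 2.76. Pcdha4, a protocadherin gene, was at -2.91, Foxp4 at -2.22 (0.53 on another probe) and Kcnk3 at -2.04. Reln was at least 16.1-fold higher and Adam12 at least 18.3-fold lower. Differences this large depended on how dim signal was handled. In all, 25 genes were at least 4-fold higher and 31 lower, but 6 and 4 for probes well above background on all 4 arrays. With normexp the counts were 3 and 2. Of the 28 genes past 2-fold with another measured probe, 21 had every other probe in the same direction and 8 (28.6%) had another probe at 2-fold.

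To see whether the antibody moved sDCs towards maDCs, the genes 2-fold apart in both comparisons were counted among 13013 genes measured in both. Of 1693 genes higher in sDCs than in maDCs, 25 were lower and 2 higher with the antibody, against 9.11 and 6.37 expected of independent lists. Of 1819 lower genes, 22 were higher and 19 lower, against 6.85 and 9.78. Thus 47 of 68 (69.1%, exact 95% binomial interval of the share 0.567 to 0.798, which treats genes as independent) went towards maDCs. The whole profile did not come closer to maDCs with the antibody. Over the 12946 genes well above background on every array, the SD of differences from maDCs was 1.31 with it and 1.30 without. Against imDCs the SD was 1.53 with the antibody and 1.57 without. The share therefore describes these 68 genes and not the profile. The 2 comparisons behind the 68 genes share the sDC array: differences correlated at -0.0887 across genes with a covariance of -0.0300, against -0.0447 and -0.00629 in simulated arrays with spot noise alone. In those simulations a median of 0 genes was 2-fold apart with the antibody. That count was nearly fixed in advance, as the noise came from replicated probes with all spots well above background. It was small beside 2-fold, was added alike at every signal level, and held no noise of labelling or culture. The simulated correlation and covariance carry the same limit. With the 2 differences taken from separate probes of a gene, 9 of 19 (share 0.474) were opposite, and for such genes with both differences from 1 probe, 9 of 12 (0.75). The antibody difference then came from the dimmer probe. On it 22 genes were 2-fold higher and 24 lower with the antibody, against 8 and 16 on the brighter probe. Among the 22 genes lower in sDCs and higher with the antibody, 6 were neutrophil list members, Camp, Chil3, Ctsg, Elane, Ltf and Ngp. Cma1 and Hdc were on the mast cell and basophil list, and Prg2 was on the eosinophil list. Of the 25 genes higher in sDCs and lower with the antibody, 1 (Serpinh1) was on the stromal list, and Cd70 was on the costimulation list. The others in both sets, such as Chil4 and Cd248, were on no list, so their cell of origin was not assessed.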

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

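All 6 alternatives were planned. Of 48 recomputed counts of genes, 40 stayed within 1.5 times and 8 did not. With no filter on dim probes, 6221 genes were higher in maDCs than in imDCs (3045 with it) and 6170 in sDCs than in imDCs (3817), as near-background values enter. For antibody-treated sDCs against sDCs, with 124 higher and 181 lower, the counts were 309 and 584 with no filter, 47 and 65 for probes well above background on all 4 arrays, which leaves fewer genes, and 44 and 44 with normexp and its offset of 50, which were not tried apart. The share of genes going back towards maDCs, 0.691, was 0.842 with normexp, over fewer genes, and 0.677 to 0.771 in the other 5. Of the list medians, 522 values moved by under 0.23 log2 units (the largest 95th percentile of the SD between spots of replicated probes well above background, scaled to a difference), 115 by more, and 2 reversed, counting only lists outside the middle 95% of random lists: Notch for sDC minus maDC (-1.18, 0.31 over probes well above background on all 4 arrays) and glycolysis and hypoxia for antibody-treated sDC minus sDC (0.0067, -0.0027 with normexp), the cause not tested. In all, 28 values had a changed sign, the other 26 in lists within that middle 95%. Of the values of named genes, 2471 moved by less, 682 by more and 1 reversed: Fdft1 for maDC minus imDC, at -1.22 and at 0.64 as the mean over probes, since its other probe lay at 2.49. Of 431 values of named genes past 2-fold, 423 kept it in the same direction under quantile normalization, 427 in the authors' table and 407 with normexp. Most of these genes were picked for large differences on the same arrays, so few could be expected to drop out. Scaling by spike-ins was not run, because 59 to 72 of 320 such spots per array were well above background, with a median signal of 6.03 to 8.12 where the 75th percentile of all spots was 1310 to 1994. Signal over background limits the comparison with the antibody most, where 64 of the 124 higher and 71 of the 181 lower genes are bounds. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers.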

Other observations

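Of the tests in this part, that of whether a lower stromal share raised all other cell types alike was chosen only after the list medians had been seen, and the others were written before their results. In maDCs 4 of 9 osteoclast markers were at least 2-fold higher than in imDCs and 1 lower (median 0.79, percentile 97.7), with the acid phosphatase gene Acp5 at 3.28. In sDCs 5 of 9 were lower and 3 higher than in maDCs (median -2.20, percentile 0), with the cell fusion gene Dcstamp at -7.44 and Acp5 at -4.13, against the gelatinase gene Mmp9 at 1.84. Against imDCs the sDC median was -0.85 (percentile 2.77, 2 higher and 4 lower), turning to 0.13 with the mean over probes, and with the antibody it was 0.09, with none of 9 genes 2-fold apart. Plasmacytoid DC genes were lower in sDCs than in maDCs in 4 of 8 cases and higher in 2 (median -1.85, percentile 0.1), with Pacsin1 at -3.52 and Spib at -3.43. Against imDCs 5 of 9 were lower and 3 higher (median -1.77, percentile 0.06). From imDCs to maDCs 4 of 9 were higher and 3 lower (median 0.21, percentile 47.6, and -0.16 with no filter on dim probes), and none of 8 was 2-fold apart with the antibody (median -0.01, turning positive in 4 of 6 alternatives, to 0.01 under quantile normalization).

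Of 13 haematopoietic progenitor genes 10 were at least 2-fold lower in sDCs than in maDCs and 1 higher (median -2.36, percentile 0.01), with Myb at -5.86, and Gata2 at -7.59 and Kit at -5.16, both also on the mast cell and basophil list (median -6.60), and 7 were lower and 2 higher than in imDCs (median -1.07 or lower, percentile 0.395). The median was 0.70 for maDC minus imDC (4 of 12 higher, 2 lower) and -0.18 with the antibody (none of 11 genes 2-fold apart). Cholesterol synthesis genes were lower in sDCs, with 10 of 19 lower and 1 higher than in imDCs (median -1.05, percentile 0) and 6 lower and 1 higher than in maDCs (median -0.79, percentile 0.03). Fdps, which makes farnesyl diphosphate, was at -3.46 and -1.40 in these comparisons and at -2.06 for maDC minus imDC, where 4 of 19 genes were lower (median -0.44, percentile 0.96), and the antibody median was -0.13 (percentile 0.14, none 2-fold apart). B cell genes had medians of 0.99 for maDC minus imDC (3 of 7 higher), 1.41 for sDC minus imDC (5 of 9 higher), 0.61 for sDC minus maDC (3 of 8 higher, 1 lower) and -0.02 with the antibody, and Ms4a1, which encodes CD20, was 4.90 higher in sDCs than in imDCs. T and NK cell genes had medians of 0.67, -0.37, -0.74 and 0.10 in the same order, with Gzma at least 239-fold higher in maDCs than in imDCs, and erythroid and megakaryocyte genes 0.67, -0.72, -1.08 and -0.22, with Car2 at -7.60 in sDCs against imDCs. The erythroid and megakaryocyte percentiles were 89.3, 2.17, 1.085 and 2.41, and with the antibody 2 of 9 members were lower and none higher. The handling list was at -0.28 for sDC minus maDC (percentile 9.56), where the small heat shock protein gene Hspb1 was higher by 4.12.

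Stromal transcripts were abundant in the sDC profile, Col1a1 lying at 5.57 and Col3a1 at 4.77 log2 units above the array's 75th percentile. The stromal list (1 gene is on another list, and 20 of 26 genes were well above background in maDCs, grown without a stromal layer) was higher in sDCs than in maDCs in 80.8% of members. This share restates the pattern: stromal cells or their RNA carried over from the co-culture and expression of matrix genes by the sDCs themselves would both give it and cannot be told apart, since no array of the stroma alone was analysed here. The labels call the sDCs purified. Dilution by stromal RNA as the whole of the low class II level is argued against: 12 genes expressed by all leukocytes had a median of 0.29 for sDC minus maDC (95% range of the median from order statistics -0.23 to 0.70), and the class II list -3.93 or lower. No biological explanation was tested.

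More genes lay 2-fold apart between sDCs and imDCs than between sDCs and maDCs, by a ratio of 1.38, and the imDC array came from another slide. If its signal distribution alone were the source, quantile normalization could be expected to bring the ratio to 1 or below, yet it stayed at 1.32 (bootstrap over genes 1.29 to 1.35). For maDC minus imDC, which crosses the same slides, the ratio to sDC minus maDC was 0.952. Slide effects on single probes, and the longer culture, LPS, the starting cells and the stromal layer, stay open and cannot be told apart from the group.

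Whether the share of genes going back towards maDCs with the antibody, 69.1%, comes in part from noise of the sDC array could not be decided. With separate probes it was 0.474 (exact interval 0.244 to 0.711), against 9 of 12 (0.75) for such genes with both differences from 1 probe. But 19 and 12 genes are too few, and the separate probe was the dimmer one, so its own noise may also lower the share. Simulated spot noise alone put a median of 0 genes 2-fold apart with the antibody. This decides nothing, since that noise was small beside 2-fold and left out dim signal, labelling and culture. Lower stromal (median -0.78, SD over members 0.34) and higher neutrophil transcripts (1.10, SD 0.58) also differed between the same arrays. The neutrophil and macrophage lists were not raised alike, as the neutrophil median lay above the macrophage median by 1.23 (bootstrap over genes 0.68 to 1.77). That test was set after both medians had been seen. It restates them and cannot weigh a lower stromal share as a cause. Differences in cell makeup between the 2 cultures, a lower stromal share among them, and an effect of IL-10 neutralization itself stay open, and no biological explanation was tested.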
